A study of Homo sapiens with 16 samples.

How the data were processed

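Total RNA came from PC3 cells seeded in flasks, given compound or vehicle on the next day and kept for 48 h at 0.2 % or 21 % oxygen. It was amplified with a NuGEN Ovation system, labelled with biotin and hybridised to Affymetrix U133 Plus 2 arrays, 1 array per sample. The design crosses 2 oxygen levels with 4 treatments in 8 groups of 2 arrays. Replicates were taken as the titles give them. The NO-sulindac arrays titled 2 and 2b share 1 source name per oxygen level and were taken as 2 samples, with an alternative that averages them into 1. The p-values measure only the spread between these arrays, which may be technical for the arrays titled 2 and 2b, and 2 samples per group limit the precision.

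The values are the log2 probe set values deposited by the authors, 1 column per array, already normalised between arrays. RMA and MAS5 are named in the submitters' processing notes with no role, order or version, and background correction and filters are not given in the sources used here. That the values are on the log2 scale was inferred from the deposited values: every column ran from about 2 to about 15 (2.02 to 15.06), as RMA summaries of array intensities do, and the array medians lay between 6.28 and 6.36. No further normalisation was applied. No genome build or coordinates enter the results, since each gene is read by probe sets named with the gene symbols of the annotation supplied with the table.

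The table holds 54675 probe sets. The 62 control probe sets were kept out of the tests and used only as a measure of RNA quality, as the log2 difference between the 3′ and 5′ probe sets of ACTB and GAPDH. Of the others, 41091 carry 1 gene symbol, 1801 several and 11721 none. Symbols were checked through their Entrez identifiers, of which 41043 are in the reference, and 0 symbols changed. Each of the 19775 genes was represented by its probe set with the highest mean over the 16 arrays, since 10523 genes have more than 1. Genes with a mean below 4.60, the 25th percentile of the non-control probe sets, were left out, which leaves 16003 genes. The 8562 probe sets above that level with no or several symbols were tested apart.

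The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. All 16 arrays entered 1 limma fit (lmFit and eBayes, neither trend nor robust) with a mean per group, which gave 8 residual and 3.58 prior degrees of freedom. The 12 comparisons are contrasts of group means, and an interaction is the compound effect against DMSO in hypoxia minus that in normoxia. Tests are two-sided, adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The median of the 95 % confidence half-widths was 0.188 for a comparison of 2 groups and 0.266 for an interaction, on the log2 scale. Replicate numbers were not used to pair samples. In 15 pairs of groups, the differences between replicates 1 and 2 correlated across genes at r from -0.182 to 0.381, above 0.1 in 6 pairs and below -0.1 in 5.

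The 36 gene lists hold 977 memberships, of which 885 had a gene probe set before the filter on low means. They were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives, except where a choice is said to have come later. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and needed at least 5 tested members. In the text glycolysis stands for glycolysis and glucose uptake, fatty acid oxidation for fatty acid oxidation and PPAR targets, and extracellular matrix for extracellular matrix, invasion and mesenchymal genes. They cover oxygen, metabolism, stress, inflammation, the cell cycle, DNA repair, cell identity and markers of other cell types. Named genes are the 10 largest rises and the 10 largest falls past the threshold whose groups do not overlap (for an interaction, the largest past the threshold), up to 4 members past the threshold of each list that passed, and PTGS1, PTGS2, HMOX1, VEGFA, GDF15 and HIF1A whatever their p. Where fewer than 5 genes passed, all of these and the 5 with the smallest p are named. Not every gene the rule takes is printed, and 1 further gene that it fixes beside these 6, with some list members, is not reported here. Genes that rose or fell with oxygen in untreated cells were tested as sets by camera in the compound comparisons, which share no array with that choice.

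The procedure was tested on simulated data with the groups of NO-sulindac against DMSO in hypoxia. Spread was taken from the fit of all groups, and changes of 3 sizes were added to some genes. The procedure recovered 68.7 % of 67 genes changed by 0.5 on the log2 scale. Recovery was 100 % of 67 genes changed by 1 and 100 % of 66 genes changed by 2. The 196 calls held 10 false calls and 7 of 40 genes of a list shifted by less. A comparison without added changes gave 0 calls. Few of the 16003 simulated genes were changed, whereas 4408 genes passed in the real comparison. Simulated arrays were independent, whereas the arrays titled 2 and 2b may be 1 culture. Recovery and false calls depend on both, so these values describe the simulated setting and not the real comparison. The alternatives were no filter, a filter at the median (6.32, 11886 genes), every probe set in place of 1 per gene, repeated quantile normalisation, a variance prior with trend and robust, the replicate number as a block, the averaged NO-sulindac arrays, untreated cells as the control, the compared groups alone, an estimated inter-gene correlation, oxygen sets limited to 2-fold changes, and each array left out in turn. Where leaving out an array leaves 1 in a group, that array is assumed to vary like the other groups. Crossing the replicate numbers of the hypoxia group in the oxygen comparisons was added after seeing the data, as were an estimated correlation for the oxygen sets limited to 2-fold and every probe set for a wider family of histone genes. Groups of 2 arrays are too small for tests of outlying samples or of other splits of the samples. Intensity files and the authors' enrichment results were not used here.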

Results

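Gene expression was measured on 16 Affymetrix U133 Plus 2 arrays in PC3 cells, a hormone-insensitive human prostate cancer line. The cells were kept for 48 h at 0.2 % oxygen (hypoxia) or 21 % oxygen (normoxia). At each oxygen level they were untreated or given 0.05 % DMSO (the vehicle), 25 µM sulindac or 25 µM NO-sulindac. Sulindac is a non-steroidal anti-inflammatory drug, a class whose targets are the cyclooxygenases encoded by PTGS1 and PTGS2. Cyclooxygenase activity was not measured here. NO-sulindac (NCX1102) is sulindac carrying a nitrate group that can release nitric oxide. Each of the 8 groups had 2 arrays. The NO-sulindac arrays of each oxygen level were titled replicates 2 and 2b and shared 1 source name, so they may come from 1 culture. Values are the deposited log2 probe set summaries, which ran from 2.02 to 15.06 with array medians between 6.28 and 6.36, and the number of arrays limits their precision. The SD of the log2 difference between the arrays of a group ranged from 0.121 in untreated hypoxia to 0.178 in normoxia DMSO. It was 0.160 and 0.166 for the NO-sulindac arrays in hypoxia and normoxia. Changes are given as log2 differences ± standard error from limma (n = 2 arrays per group), with p-values adjusted by Benjamini-Hochberg over 16003 genes. A gene is said to have risen or fallen when its adjusted p was under 0.05, and for every named gene that did so in a comparison of 2 groups, both arrays of 1 group lay above both arrays of the other. For each gene list, the numbers of members that rose and fell are followed, where these differ, by the numbers adjusted over the list alone. A list is said to have risen or fallen by camera, adjusted over the 36 lists of its comparison.

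Hypoxia against normoxia in DMSO-treated cells gave the oxygen response in the presence of vehicle. The largest rises were in SCNN1G, an epithelial sodium channel subunit (4.49 ± 0.16), and ANGPTL4, a secreted lipase inhibitor induced by hypoxia (4.30 ± 0.10, 19.7-fold). SLAMF9 (3.91 ± 0.08), LOX, a collagen cross-linking enzyme (3.22 ± 0.08), and the mucin MUC1 (2.90 ± 0.08) followed. BEND5, LYPD3, CFAP96, LOC154761 and PPFIA4 rose by 2.90 to 3.12. The largest falls were in FSIP1 (-2.99 ± 0.10), CHAC1, a glutathione-degrading enzyme (-2.88 ± 0.08), and RAB39B (-2.81 ± 0.15). KCNT2, SYT11, KRT20, PKHD1, KCNU1, JDP2 and IL1RL1 fell with changes from -2.44 to -2.15. Of 14 other probe sets of these genes 12 moved in the same direction, with exceptions in SCNN1G (0 of 1) and IL1RL1 (2 of 3). In all, 7011 genes passed, of which 3056 rose and 3955 fell, and 336 rose and 174 fell at least 2-fold.

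Among the fixed lists in this comparison, 33 of 38 hypoxia response genes rose and 2 fell (median 0.96), with ADM, a vasodilator peptide (2.25 ± 0.08), and the glycolytic regulator PFKFB4 (2.23 ± 0.06) near the top. Of 18 glycolysis and glucose uptake genes 16 rose and 1 fell (median 0.47), among them the glucose transporter SLC2A1 (2.31 ± 0.08) and the enzymes ALDOC (1.56 ± 0.07) and ENO2 (1.50 ± 0.09). In the opposite direction, 27 of 33 integrated stress response genes (targets of the transcription factor ATF4) fell and 2 rose (median -0.72), with asparagine synthetase ASNS at -1.99 ± 0.06 and the pseudokinase TRIB3 at -1.95 ± 0.06. Cholesterol synthesis and uptake genes rose in 12 of 19 cases and fell in 2 (median 0.31), including the sterol carrier STARD4 (1.59 ± 0.09). NF-kB and inflammatory genes rose in 11 of 26 cases and fell in 2 (median 0.23), including the NF-kB inhibitor TNFAIP3 (1.24 ± 0.07). These 5 lists also passed with an estimated correlation, at adjusted p = 0.00119, 0.017, 0.0077, 0.0475 and 0.0288 in the order given.

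The other lists that passed camera here did so only with its preset correlation. G2 and M phase genes rose in 27 of 50 cases and fell in 5 (29 and 6 adjusted over the list alone; median 0.22; adjusted p = 0.131 with an estimated correlation), with the mitotic kinase CDK1 at 0.64 ± 0.10. For S phase and DNA replication, 19 of 46 rose and 5 fell (median 0.13; adjusted p = 0.299 with an estimated correlation), with cyclin CCNE2 at 1.04 ± 0.17. Epithelial markers rose in 8 of 12 cases (9 adjusted over the list alone; median 0.27; adjusted p = 0.299 with an estimated correlation). Interferon-stimulated genes fell in 18 of 29 cases and rose in 3 (19 and 3 adjusted over the list alone; median -0.28; adjusted p = 0.351 with an estimated correlation), with MX2 at -0.86 ± 0.07 and, in the other direction, the RNA exonuclease ISG20 at 1.96 ± 0.07. Ribosome biogenesis genes fell in 16 of 30 cases and rose in 1 (median -0.17; adjusted p = 0.373 with an estimated correlation). Metallothionein and zinc handling genes (8 of 12 rose, 3 fell; median 0.39) and extracellular matrix genes (17 of 41 rose, 11 fell, 19 and 11 adjusted over the list alone; median 0.16) had adjusted p = 0.351 and 0.299 with an estimated correlation, and lost the call with the filter at the median and without hypoxia DMSO replicate 2. The metallothionein and zinc call was also lost without normoxia DMSO replicate 1 and the matrix call without normoxia DMSO replicate 2. PTGS2 rose by 2.01 ± 0.11. GDF15, a stress-induced cytokine, was 2.01-fold lower on the linear scale (1.92 to 2.10 over 1 standard error). The heme oxygenase HMOX1 rose by 0.36 ± 0.09 (adjusted p = 0.0049), while PTGS1 (-0.18 ± 0.16) and HIF1A (-0.17 ± 0.11), the oxygen-regulated transcription factor subunit, did not pass. VEGFA, an angiogenic factor, was at 0.16 ± 0.08 and did not pass, but with every probe set tested its probe set of smallest p was at -0.46. A measure of RNA quality differed between these groups: the 3′ minus 5′ log2 signal of the ACTB control was 1.78 ± 0.173 (SD, n = 2) in hypoxia DMSO and 2.42 ± 0.0567 in normoxia DMSO, against 2.40 ± 0.0682 and 2.24 ± 0.0869 in untreated hypoxia and normoxia. The GAPDH control was at 0.22 ± 0.0324 in hypoxia DMSO and 0.26 ± 0.0222 in normoxia DMSO, against 0.317 ± 0.00563 and 0.209 ± 0.0458 in untreated hypoxia and normoxia.

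Hypoxia against normoxia in untreated cells asked the same without vehicle and shares no array with the DMSO comparison. ANGPTL4 (4.42 ± 0.10), SCNN1G (4.04 ± 0.16), SLAMF9 (3.71 ± 0.08), PPFIA4 (3.39 ± 0.06) and LYPD3 (3.28 ± 0.09) rose most. LOX rose by 3.26 ± 0.08, and BEND5, CFAP96, LOC154761 and the secreted hormone STC1 by 2.88 to 3.23. FSIP1 and RAB39B (both -3.23, SE 0.10 and 0.15), CHAC1 (-2.78 ± 0.08) and KCNU1 (-2.77 ± 0.18) fell most, followed by IL1RL1, LVRN, CCDC102B, KRT20, COL8A1 and ASNS with changes from -2.46 to -2.05. Of 7004 genes that passed, 3438 rose and 3566 fell, with 350 and 187 at least 2-fold. Of 11 other probe sets of the genes named 9 moved in the same direction, with exceptions again in SCNN1G (0 of 1) and IL1RL1 (2 of 3). Across the 16003 genes, which are not independent replicates, the oxygen effects in DMSO and in untreated cells correlated at r = 0.847 (rho = 0.762), and 105 genes passed in opposite directions.

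In untreated cells 35 of 38 hypoxia response genes rose and 2 fell (median 0.96), and 16 of 18 glycolysis genes rose and 1 fell (median 0.48), with SLC2A1 at 2.20 ± 0.08. Stress response genes of the ATF4 list fell in 28 of 33 cases and rose in 1 (29 and 1 adjusted over the list alone; median -0.78), with TRIB3 at -1.98 ± 0.06. NF-kB and inflammatory genes rose in 13 of 26 cases and none fell (14 adjusted over the list alone; median 0.28), with the chemokine CXCL3 at 0.91 ± 0.07. With an estimated correlation these lists had adjusted p = 0.00144, 0.0176, 0.00259 and 0.0176. Interferon-stimulated genes fell in 19 of 29 cases and rose in 2 (21 and 2 adjusted over the list alone; median -0.32; adjusted p = 0.168 with an estimated correlation), among them IFI44L (-0.81 ± 0.06) and RSAD2 (-0.81 ± 0.06). For S phase, 22 of 46 rose and 6 fell (27 and 7 adjusted over the list alone; median 0.23), and for G2 and M phase, 29 of 50 rose and 5 fell (30 and 5 adjusted over the list alone; median 0.24), with adjusted p = 0.161 and 0.0973 with an estimated correlation. Cholesterol genes (11 of 19 rose, 2 fell; median 0.37) and ribosome biogenesis genes (16 of 30 fell, 1 rose, 18 and 1 adjusted over the list alone; median -0.21) had adjusted p = 0.0749 and 0.213 with an estimated correlation. Epithelial markers rose in 8 of 12 cases (median 0.34; adjusted p = 0.275 with an estimated correlation), and genes of the mitochondrial ribosome and TCA cycle fell in 17 of 29 cases and rose in 5 (median -0.27; adjusted p = 0.437 with an estimated correlation). The calls of the extracellular matrix (18 of 41 rose, 8 fell, 19 and 8 adjusted over the list alone), metallothionein and zinc handling (7 of 12 rose, 3 fell, 9 and 3 adjusted over the list alone) and immediate early lists (8 of 20 rose, 3 fell, 9 and 3 adjusted over the list alone) were lost with the filter at the median. They had adjusted p = 0.168, 0.364 and 0.168 with an estimated correlation. PTGS2 rose by 2.52 ± 0.11 and HMOX1 by 0.66 ± 0.09, and GDF15 changed by -1.12 ± 0.06. HIF1A (-0.17 ± 0.11), PTGS1 (-0.15 ± 0.16) and VEGFA (-0.06 ± 0.08) did not pass, although 1 VEGFA probe set was at -0.21 when every probe set was tested.

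NO-sulindac against DMSO in hypoxia is the comparison named in the title of the series. Inflammatory and interferon genes rose and DNA replication genes fell. The cytokine IL6 rose by 2.46 ± 0.09 (5.5-fold), the chemokine CXCL3 by 2.12 ± 0.07 and interferon beta, IFNB1, by 2.12 ± 0.14. The histone genes H2BC17 (2.17 ± 0.15), H2AC8 (2.13 ± 0.07) and H4C5 (1.99 ± 0.10), the adhesion molecule CEACAM5 (2.14 ± 0.08), the retinol dehydrogenase DHRS9 (2.04 ± 0.08), GRASLND (1.98 ± 0.06) and ADAMTS15 (1.95 ± 0.08) completed the largest rises. The largest falls were in the replication-associated protease FAM111B (-2.83 ± 0.09), the cell cycle transcription factors E2F2 (-2.22 ± 0.07) and E2F8 (-1.80 ± 0.11), cyclin CCNE2 (-2.10 ± 0.17), GABBR2 (-1.95 ± 0.11), NEURL1B (-1.91 ± 0.22), WDR76 (-1.86 ± 0.10), SCNN1G (-1.84 ± 0.16) and the VEGF receptor FLT1 (-1.81 ± 0.12). SOX6 changed by -1.93 ± 0.12 against DMSO but by -0.93 against untreated cells.

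Of 46 S phase and DNA replication genes tested in hypoxia, 39 fell and none rose under NO-sulindac (41 and 0 adjusted over the list alone; median -0.60), including the helicase subunit MCM4 (-1.79 ± 0.08) and the origin factor ORC1 (-1.46 ± 0.13). G2 and M phase genes fell in 31 of 50 cases and rose in 3 (32 and 3 adjusted over the list alone; median -0.33), with topoisomerase TOP2A at -1.27 ± 0.06 and CDK1 at -1.19 ± 0.10. DNA repair genes fell in 21 of 33 cases and rose in 1 (22 and 1 adjusted over the list alone; median -0.40), with the exonuclease EXO1 at -1.27 ± 0.11 and BARD1 at -1.17 ± 0.07. Interferon-stimulated genes rose in 21 of 29 cases and fell in 1 (24 and 1 adjusted over the list alone; median 0.43), with OASL at 1.74 ± 0.08, HERC5 at 1.36 ± 0.06 and RSAD2 at 1.36 ± 0.06. NF-kB and inflammatory genes rose in 13 of 26 cases and fell in 2 (14 and 4 adjusted over the list alone; median 0.39), among them the chemokines CXCL2 (1.88 ± 0.06) and CCL20 (1.87 ± 0.12). Stress response genes of the ATF4 list rose in 21 of 33 cases and fell in 2 (23 and 3 adjusted over the list alone; median 0.42), with ATF3 at 1.33 ± 0.09, CEBPB at 1.07 ± 0.07, ASNS at 0.98 ± 0.06 and DDIT3 at 0.92 ± 0.07. Immediate early genes, which respond within minutes to growth factors and stress, rose in 10 of 20 cases and none fell (median 0.24), with the mRNA-destabilising protein ZFP36 at 1.30 ± 0.13. In the hypoxia response list 20 of 38 genes fell and 3 rose (22 and 3 adjusted over the list alone; median -0.22), with LOX at -0.98 ± 0.08 and ANGPTL4 at -0.84 ± 0.10. When the correlation was estimated, these 8 lists passed at adjusted p = 0.00352, 0.00959, 0.0178, 0.0178, 0.0113, 0.00959, 0.0178 and 0.0189 in the order given.

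Smaller groups of hypoxic cells' genes also moved under NO-sulindac. Fatty acid synthesis genes fell in 6 of 14 cases (median -0.20), with the regulator SREBF1 at -0.65 ± 0.06, and prostaglandin genes rose in 6 of 22 cases (median 0.15), with the prostaglandin E receptors PTGER2 (1.12 ± 0.08) and PTGER4 (0.83 ± 0.08). Each had adjusted p = 0.047 with an estimated correlation. Core histone genes rose in 8 of 14 cases and fell in 2 (8 and 3 adjusted over the list alone; median 0.47; adjusted p = 0.0295 with an estimated correlation), with H4C8 at 1.53 ± 0.07, but with every probe set tested the list median was 0.0068 and the call was lost (p = 0.211). The lists of NRF2 antioxidant targets (11 of 25 rose, 1 fell; median 0.13), endoplasmic reticulum chaperones (10 of 24 rose, 1 fell, 11 and 1 adjusted over the list alone; median 0.16), glycolysis (3 of 18 fell; median -0.12), autophagy (10 of 31 rose, 3 fell; median 0.045) and metallothioneins and zinc handling (9 of 12 rose, 2 fell; median 0.22) had adjusted p = 0.0915, 0.103, 0.109, 0.0915 and 0.263 with an estimated correlation. The calls for autophagy and for metallothioneins and zinc handling were also lost without DMSO replicate 1 and in a fit of the compared groups alone. Among their members, the aldo-keto reductase AKR1C1 was at 1.21 ± 0.08, HMOX1 at 1.02 ± 0.09 and SLC2A1 at -0.70 ± 0.08, with another SLC2A1 probe set at -1.16. GDF15 rose by 1.52 ± 0.06, and PTGS2 by 0.69 ± 0.11 against DMSO and 0.41 against untreated cells. PTGS1 (0.35 ± 0.16), HIF1A (0.07 ± 0.11) and VEGFA (-0.07 ± 0.08) did not pass, although 1 VEGFA probe set was at 0.79 when every probe set was tested.

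With untreated cells as control, 2007 genes rose and 2736 fell under NO-sulindac in hypoxia, so the balance of rises and falls depended on the control. In hypoxia 4408 genes passed for NO-sulindac against DMSO, of which 2310 rose and 2098 fell, and 102 rose and 105 fell at least 2-fold. The count was 2795 with the NO-sulindac arrays of an oxygen level averaged into 1 sample, 2773 without hypoxia NO-sulindac replicate 2 and 2790 without hypoxia DMSO replicate 2. Lists without a call included heat shock proteins (5 of 19 rose, 4 fell), apoptosis regulators (4 of 24 rose, 4 fell), Wnt targets (3 of 19 rose, 5 fell, 4 and 5 adjusted over the list alone) and AHR targets (3 of 7 rose, 3 rose and 1 fell adjusted over the list alone). The same held for nitric oxide and cGMP signalling (6 of 18 rose, 2 fell, 6 and 3 adjusted over the list alone; median 0.007), oxidative phosphorylation (2 of 47 rose, 2 fell), cytosolic ribosomal proteins (1 of 38 rose, 0 adjusted over the list alone) and iron handling (6 of 14 rose, 1 fell, 7 and 1 adjusted over the list alone). No call was made either for p53 targets (7 of 21 rose, 2 fell, 8 and 2 adjusted over the list alone), fatty acid oxidation (7 of 17 rose, 3 fell, 8 and 4 adjusted over the list alone), extracellular matrix (11 of 41 rose, 14 fell, 11 and 15 adjusted over the list alone) and angiogenic factors (7 of 26 rose, 5 fell, 7 and 6 adjusted over the list alone). Nor was one made for ribosome biogenesis (6 of 30 rose, 3 fell, 7 and 4 adjusted over the list alone), mitochondrial ribosome and TCA cycle (4 of 29 rose, 2 fell, 3 and 2 adjusted over the list alone), epithelial markers (4 of 12 rose, 2 fell) and cholesterol genes (1 of 19 rose, 2 fell). Markers of other cell types did not pass as lists either: 1 of 12 luminal prostate genes rose and 4 fell, 2 of 6 endothelial genes rose, 1 of 14 fibroblast genes rose and 3 fell (2 and 3 adjusted over the list alone), and 1 of 11 leukocyte genes rose and 1 fell. The ACTB 3′ minus 5′ signal was 1.86 ± 0.0016 (SD, n = 2) in hypoxia NO-sulindac, beside the 1.78 of hypoxia DMSO. GAPDH was at 0.224 and 0.22.

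**Figure D1:**
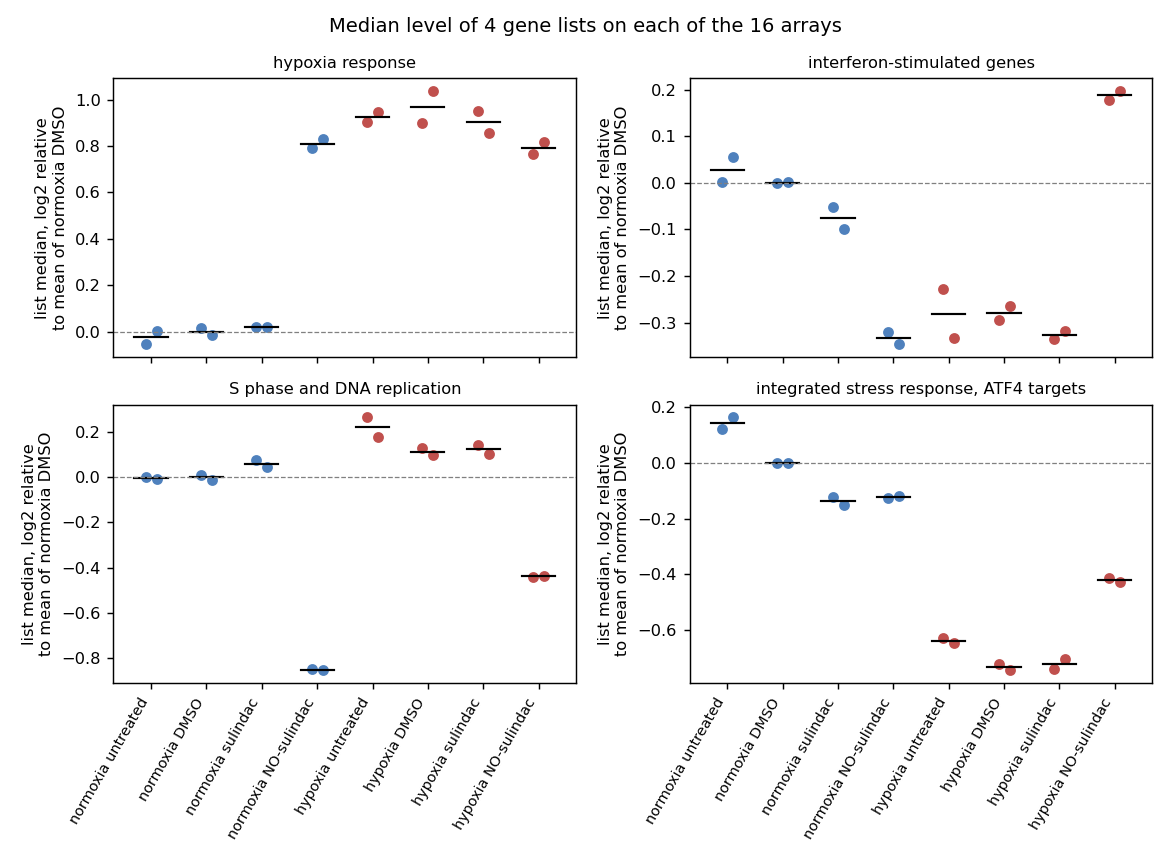
Median log2 level of 4 gene lists per array (vertical axis), relative to the mean of the normoxia DMSO arrays, for the 8 groups (horizontal axis; blue normoxia, red hypoxia); points are arrays and lines the mean of the 2 arrays of a group. The lines of the hypoxia response list lay at 0.81 in normoxia NO-sulindac and 0.968 in hypoxia DMSO, and those of the interferon-stimulated list at 0.188 in hypoxia NO-sulindac and -0.333 in normoxia NO-sulindac.

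NO-sulindac against DMSO in normoxia showed the compound's effect at atmospheric oxygen. DHRS9 rose by 4.11 ± 0.08 (17.2-fold), the chemokine receptor CXCR4 by 3.81 ± 0.11, CEACAM5 by 3.75 ± 0.08 and the cell cycle regulator RGCC by 3.49 ± 0.11. FA2H (3.26 ± 0.10), ANGPTL4 (3.20 ± 0.10), the trypsin inhibitor SPINK1 (3.12 ± 0.11), the epithelial transcription factor ELF3 (3.02 ± 0.06), HMOX1 (2.75 ± 0.09) and ZFP36 (2.70 ± 0.13) followed. FLT1 (-2.89 ± 0.12), CBLN2 (-2.41 ± 0.12), RUNDC3B (-2.40 ± 0.09), the histone gene H3C3 (-2.40 ± 0.07) and the RNA-binding protein gene IGF2BP1 (-2.39 ± 0.23) fell most, followed by PRND, FAM111B, FBXO43, KCNT2 and E2F8 with changes from -2.36 to -2.10. In total 7308 genes passed, of which 3029 rose and 4279 fell, and 368 rose and 312 fell at least 2-fold. Of 17 other probe sets of the genes named 15 moved in the same direction, and for FLT1 this held for 2 of 4.

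In normoxia, with oxygen unchanged, NO-sulindac raised 37 of 38 hypoxia response genes and 1 fell (median 0.81), including ADM (2.51 ± 0.08), ANKRD37 (1.93 ± 0.10) and PFKFB4 (1.76 ± 0.06). Glycolysis genes rose in 13 of 18 cases and fell in 1 (14 and 1 adjusted over the list alone; median 0.31), with SLC2A1 at 2.11 ± 0.08 and ENO2 at 1.45 ± 0.09. G2 and M phase genes fell in 46 of 50 cases and none rose (47 adjusted over the list alone; median -0.69), S phase genes fell in 42 of 46 and rose in 1 (median -0.85), and DNA repair genes fell in 27 of 33 (median -0.50). Examples are the mitotic kinase AURKB (-1.64 ± 0.08), the replication factor MCM10 (-1.76 ± 0.08) and EXO1 (-1.88 ± 0.11). Immediate early genes rose in 16 of 20 cases and fell in 1 (18 and 1 adjusted over the list alone; median 0.54), with the phosphatase DUSP1 at 1.79 ± 0.06. NF-kB and inflammatory genes rose in 13 of 26 cases and none fell (median 0.21), with CXCL3 at 1.91 ± 0.07 and IL6 at 1.41 ± 0.09. Autophagy and lysosome genes rose in 16 of 31 cases and fell in 2 (median 0.30), with the autophagy receptor SQSTM1 at 1.33 ± 0.06, and angiogenic factors rose in 15 of 26 and fell in 7 (median 0.30), with the hypoxia-inducible factor EPAS1 at 1.83 ± 0.05. With an estimated correlation these 9 lists passed at adjusted p = 0.0014, 0.0262, 0.00257, 0.00338, 0.02, 0.00338, 0.00338, 0.0114 and 0.034 in the order given.

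Further lists passed in normoxia with the preset correlation alone. Epithelial markers rose in 9 of 12 cases (10 adjusted over the list alone; median 0.41; adjusted p = 0.0749 with an estimated correlation), with the adhesion protein CDH1 at 2.13 ± 0.09. NRF2 antioxidant targets rose in 14 of 25 and fell in 2 (15 and 3 adjusted over the list alone; median 0.21; adjusted p = 0.0749 with an estimated correlation), with AKR1C1 at 2.44 ± 0.08 and AKR1C3 at 1.58 ± 0.06, members of a family of similar sequences. Metallothionein and zinc handling genes rose in 8 of 12 and fell in 1 (median 0.69; adjusted p = 0.0749 with an estimated correlation), with MT1X at 1.19 ± 0.06. Ribosome biogenesis genes fell in 23 of 30 and rose in 1 (median -0.36; adjusted p = 0.0749 with an estimated correlation), with the RNA polymerase I subunit POLR1A at -1.47 ± 0.07. Interferon-stimulated genes fell in 18 of 29 and rose in 2 (18 and 3 adjusted over the list alone; median -0.34; adjusted p = 0.12 with an estimated correlation), with IFIT5 at -1.18 ± 0.08. Mitochondrial ribosome and TCA cycle genes fell in 20 of 29 and rose in 2 (21 and 3 adjusted over the list alone; median -0.25; adjusted p = 0.275 with an estimated correlation). Extracellular matrix genes (17 of 41 rose, 7 fell, 17 and 8 adjusted over the list alone; median 0.18) and cholesterol genes (10 of 19 rose, 2 fell, 10 and 4 adjusted over the list alone; median 0.20) had adjusted p = 0.089 and 0.0749 with an estimated correlation. The calls for p53 targets (7 of 21 rose, 6 fell, 10 and 6 adjusted over the list alone), fatty acid synthesis (6 of 14 fell, 7 adjusted over the list alone), iron handling (9 of 14 rose, 3 fell), endoplasmic reticulum chaperones (8 of 24 rose) and core histones (8 of 14 rose, 5 fell) had adjusted p = 0.0794, 0.0857, 0.089, 0.173 and 0.082 with an estimated correlation. Each was lost under at least 1 other alternative. Among the p53 targets, GDF15 was at 2.31 ± 0.06, PHLDA3 at 1.94 ± 0.09 and the cell cycle inhibitor CDKN1A at 1.78 ± 0.06. The ATF4 list had no call (10 of 33 rose, 15 fell, 10 and 16 adjusted over the list alone). PTGS2 rose by 2.10 ± 0.11, and VEGFA by 0.50 ± 0.08, with another VEGFA probe set at 1.63. PTGS1 (-0.14 ± 0.16) and HIF1A (-0.03 ± 0.11) did not pass. The ACTB 3′ minus 5′ signal was 2.26 ± 0.0783 (SD, n = 2) in normoxia NO-sulindac and 2.42 ± 0.0567 in normoxia DMSO. GAPDH was at 0.231 and 0.26.

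**Figure D2:**
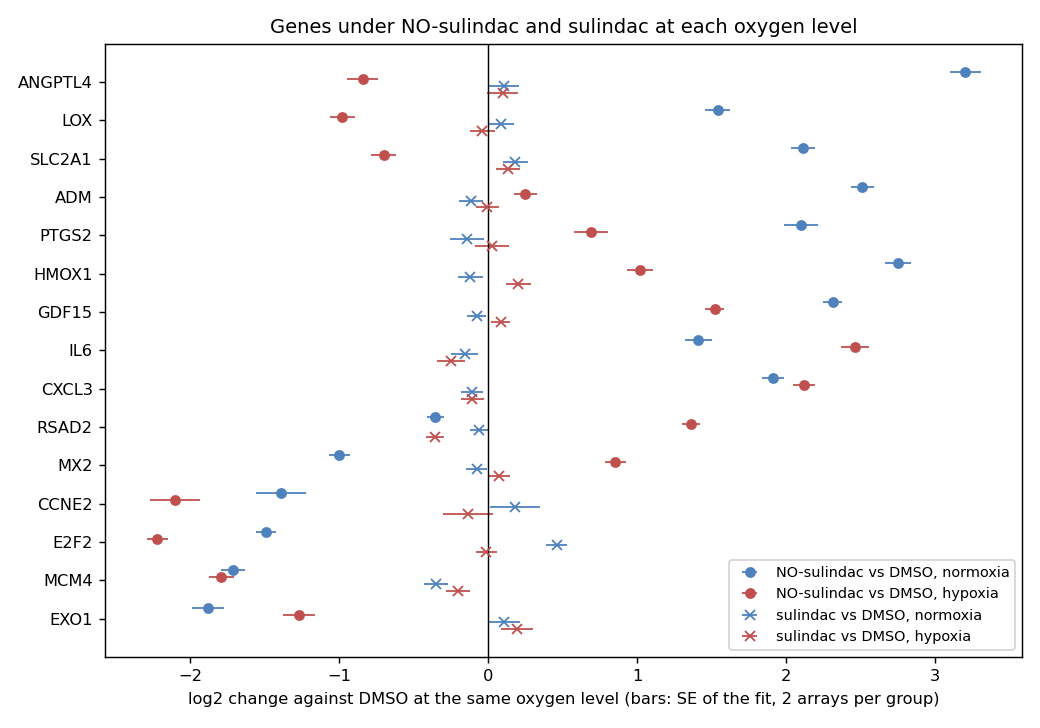
Log2 change (axis of values; points, with bars for the standard error, n = 2 arrays per group) of 15 named genes under NO-sulindac and under sulindac against DMSO at each oxygen level. ANGPTL4 was at 3.20 in normoxia and -0.84 in hypoxia under NO-sulindac, while IL6, CXCL3 and GDF15 were above 0 and CCNE2, E2F2, MCM4 and EXO1 below 0 at both oxygen levels.

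Sulindac against DMSO tested the parent compound without the nitrate group at the same dose and time. In hypoxia 1 gene passed: IFI6, an interferon-induced gene, at -0.54 ± 0.06 (limma, adjusted p = 0.0374). Against untreated cells IFI6 was at -0.16 and did not pass. The next smallest p-values were those of GUSBP4 (-0.50 ± 0.07), WT1-AS (0.93 ± 0.13), TAF15 (0.53 ± 0.08) and CBLN2 (-0.78 ± 0.12), none of which passed. In normoxia 3 genes passed: TRMT2B, a tRNA methyltransferase (-0.80 ± 0.09), the splicing factor gene HNRNPL (-0.44 ± 0.05) and the aquaporin gene AQP3 (0.43 ± 0.06), while HIC2 (0.62 ± 0.09) and E2F2 (0.46 ± 0.07) did not. Against untreated cells HNRNPL was at 0.10. TRMT2B itself fell under DMSO against untreated cells. Each of these calls was lost in a fit of the compared groups alone. At an unadjusted p under 0.05 there were 1489 genes in hypoxia and 1366 in normoxia, where chance alone gives 800. The same cut gave 2836 and 3229 genes for DMSO against untreated cells. Across genes the sulindac effects in hypoxia and normoxia correlated at r = 0.014 (rho = 0.0087). The excess thus cannot be told apart from other differences between the groups. Counts past the threshold for sulindac in hypoxia and normoxia were 33 and 24 with a variance prior with trend and robust. They were 29 and 16 with all probe sets, and 0 and 1 with no filter. The counts without 1 array ran from 0 to 11 in hypoxia and from 0 to 1 in normoxia.

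PTGS1 and PTGS2, which encode the cyclooxygenases, were at 0.12 ± 0.16 and 0.02 ± 0.11 in hypoxia and at -0.12 ± 0.16 and -0.14 ± 0.11 in normoxia under sulindac, and none of these passed. HMOX1 (0.20 ± 0.09 and -0.12 ± 0.09), GDF15 (0.08 ± 0.06 and -0.08 ± 0.06), VEGFA (-0.03 ± 0.08 and 0.00 ± 0.08) and HIF1A (-0.02 ± 0.11 and -0.04 ± 0.11) did not pass in hypoxia or normoxia. ATF4 targets fell as a list in normoxia (median -0.14, adjusted p = 4.24e-09, and 0.0224 with an estimated correlation), with none of 33 genes passing over all genes and 11 falling when adjusted over the list alone. This shift was about as large as that between the controls, DMSO against untreated cells in normoxia (median -0.139). The remaining list calls for sulindac were lost with an estimated correlation. In normoxia they were S phase (median 0.067; 3 rose and 1 fell adjusted over the list alone; adjusted p = 0.282 with an estimated correlation), interferon-stimulated genes (-0.063; 1 fell adjusted over the list alone; adjusted p = 0.388 with an estimated correlation) and NF-kB (-0.067; adjusted p = 0.211 with an estimated correlation). Further calls there were DNA repair (0.069; adjusted p = 0.41 with an estimated correlation) and fatty acid oxidation (0.064; 1 rose adjusted over the list alone; adjusted p = 0.475 with an estimated correlation). In hypoxia they were interferon-stimulated genes (median -0.039; 1 fell, 2 adjusted over the list alone) and fatty acid oxidation (0.053; 5 rose adjusted over the list alone), each with adjusted p = 0.70 with an estimated correlation. The hypoxia response list was at a median of -0.014 in hypoxia and 0.007 in normoxia, with none of 38 genes passing over all genes and, in normoxia, 1 falling when adjusted over the list alone. The 95 % confidence interval of the sulindac effect lay within a 2-fold change in either direction for 99.9 % of genes in hypoxia and 99.93 % in normoxia, and within 1.5-fold for 95.6 % and 94.9 %. The ACTB 3′ minus 5′ signal was 2.02 in hypoxia sulindac and 1.78 in hypoxia DMSO, and that of GAPDH 0.195 and 0.22. In normoxia these were 2.44 with sulindac and 2.42 with DMSO, and 0.243 and 0.26 for GAPDH.

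NO-sulindac against sulindac compared the compounds directly at the matched dose of 25 µM and 48 h. In hypoxia 4096 genes differed, 1968 higher and 2128 lower under NO-sulindac. IL6 (2.71 ± 0.09), CXCL3 (2.22 ± 0.07), H2AC8 (2.17 ± 0.07), CEACAM5 (2.08 ± 0.08) and H4C5 (2.05 ± 0.10) were higher by the largest amounts, with IFNB1, DHRS9, CCL20, H2AC15 and LINC00520 at 1.89 to 1.96. FAM111B (-2.79 ± 0.09), E2F2 (-2.21 ± 0.07), WDR76 (-2.17 ± 0.10), SOX6 (-2.08 ± 0.12) and GABBR2 (-2.03 ± 0.11) were lower by most. S phase genes were lower in 40 of 46 cases (median -0.64) and interferon-stimulated genes higher in 22 of 29 and lower in 1 (23 and 1 adjusted over the list alone; median 0.48). Hypoxia response genes were lower in 16 of 38 cases and higher in 3 (17 and 3 adjusted over the list alone; median -0.19), and ATF4 targets higher in 21 of 33 and lower in 2 (21 and 3 adjusted over the list alone; median 0.36). When the correlation was estimated, these lists had adjusted p = 0.00368, 0.012, 0.0263 and 0.00743. PTGS2 was 0.66 ± 0.11, HMOX1 0.82 ± 0.09 and GDF15 1.44 ± 0.06 higher under NO-sulindac. PTGS1 (0.23 ± 0.16), VEGFA (-0.04 ± 0.08) and HIF1A (0.09 ± 0.11) did not pass. In these groups the ACTB 3′ minus 5′ signal was 1.86 ± 0.0016 (SD, n = 2) with NO-sulindac and 2.02 ± 0.000769 with sulindac. GAPDH was at 0.224 and 0.195. The count was 2505 with the NO-sulindac arrays averaged, 2265 in a fit of the compared groups alone and 2680 without hypoxia NO-sulindac replicate 2.

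In normoxia 7583 genes differed between the compounds, 3155 higher and 4428 lower under NO-sulindac. DHRS9 (4.05 ± 0.08), CEACAM5 (3.53 ± 0.08), RGCC (3.33 ± 0.11), FA2H (3.18 ± 0.10) and CXCR4 (3.15 ± 0.11) were higher by most, and FLT1 (-2.95 ± 0.12), FAM111B (-2.50 ± 0.09), CBLN2 (-2.46 ± 0.12), IGF2BP1 (-2.45 ± 0.23) and SERTAD4 (-2.44 ± 0.13) lower by most. For FLT1 2 of 4 other probe sets moved in the same direction. Hypoxia response genes were higher in 36 of 38 cases (37 adjusted over the list alone; median 0.79), G2 and M phase genes lower in 49 of 50 (median -0.76) and S phase genes lower in 42 of 46 and higher in 1 (43 and 1 adjusted over the list alone; median -0.96). With an estimated correlation these lists had adjusted p = 0.00154, 0.00211 and 0.00267. PTGS2 was 2.25 ± 0.11, HMOX1 2.87 ± 0.09, GDF15 2.38 ± 0.06 and VEGFA 0.50 ± 0.08 higher. PTGS1 (-0.02 ± 0.16) and HIF1A (0.01 ± 0.11) did not pass. For these groups the ACTB 3′ minus 5′ signal was 2.26 ± 0.0783 (SD, n = 2) with NO-sulindac and 2.44 ± 0.0434 with sulindac. GAPDH was at 0.231 and 0.243. Oxidative phosphorylation genes were lower in 14 of 47 cases and higher in 1 (median -0.092; adjusted p = 0.441 with an estimated correlation), a call that was lost with the filter at the median. Interferon-stimulated genes were lower in 17 of 29 and higher in 5 (median -0.29; adjusted p = 0.227 with an estimated correlation).

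DMSO against untreated cells compared the vehicle with no treatment. Across the 16003 genes, which are not independent replicates, the differences in hypoxia and normoxia correlated at r = 0.031 (rho = 0.054). At both oxygen levels 8 genes rose and 10 fell, while 32 passed in opposite directions. Few genes thus passed in the same direction at both levels. A vehicle effect cannot be told apart here from other differences between the groups. In normoxia TRMT2B (-2.63 ± 0.09), VHL, the ubiquitin ligase subunit that targets hypoxia-inducible factors (-2.13 ± 0.12), MATR3 (-1.70 ± 0.08) and STRIP2 (-1.59 ± 0.08) fell most in that order. PACRGL, ATP6V0D2, FNTB, TAF8, FTX and TRIM58 fell with changes from -1.44 to -1.26. The histone gene H1-3 rose by 1.05 ± 0.09, with CHRM3-AS2, LINC00216, LINC00705, BLID, CASC7, KCNMA1-AS1, CPEB4, ZNF512B and CYP3A5 at 0.77 to 0.98. In total 786 genes passed in normoxia (354 rose, 432 fell), with 21 falling and 1 rising at least 2-fold, against 67 in a fit of the compared groups alone and 251 without normoxia untreated replicate 1. Fatty acid synthesis genes rose in 4 of 14 cases (5 adjusted over the list alone; median 0.15), and ATF4 targets fell in 2 of 33 (9 adjusted over the list alone; median -0.14), each with adjusted p = 0.0646 with an estimated correlation. In hypoxia 415 genes passed (87 rose, 328 fell). The excess of falls stayed with the filter at the median (165 rose, 713 fell) but was small with every probe set tested (496 and 540). Of the 415 genes, 1 rose at least 2-fold: the antisense transcript ZNF217-AS1 (1.27 ± 0.12). SOX6 (1.00 ± 0.12), FOLR1 (0.99 ± 0.10) and TSHZ2 (0.90 ± 0.10) followed, SYT11 (-0.84 ± 0.14) and KSR1 (-0.79 ± 0.16) had the largest falls, and no list passed. Of the other probe sets of the 20 genes with the largest changes, 15 of 19 moved in the same direction in normoxia (0 of 1 for STRIP2) and 11 of 15 in hypoxia (1 of 2 for KSR1). The hypoxia count was 11 without hypoxia untreated replicate 1 and 2 in a fit of the compared groups alone. PTGS1, PTGS2, HMOX1, VEGFA, GDF15 and HIF1A passed at neither oxygen level, and the ACTB 3′ minus 5′ signals were 1.78 in hypoxia DMSO and 2.40 in hypoxia untreated, and those of GAPDH 0.22 and 0.317.

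**Figure D3:**
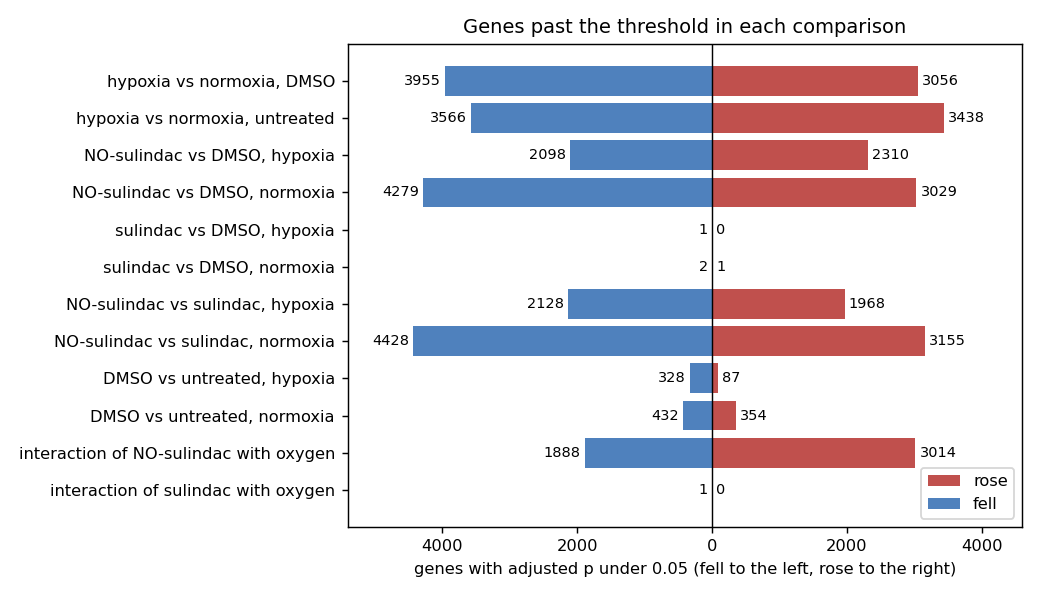
Number of genes that rose and fell (adjusted p under 0.05, limma) in each of the 12 comparisons, as bars starting at 0. For the interactions, rose means a more positive compound effect in hypoxia than in normoxia; the counts run from 1 for sulindac in hypoxia to 7583 for NO-sulindac against sulindac in normoxia.

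The interaction of NO-sulindac with oxygen tested whether its effect against DMSO differed between hypoxia and normoxia. It did for 4902 genes, of which 3014 had a more positive effect in hypoxia and 1888 a more negative one. The ACTB 3′ minus 5′ signals of the groups compared were 1.86 and 1.78 in hypoxia (NO-sulindac and DMSO) and 2.26 and 2.42 in normoxia, and those of GAPDH 0.224 and 0.22 in hypoxia and 0.231 and 0.26 in normoxia. ANGPTL4 (-4.04 ± 0.15), CXCR4 (-4.00 ± 0.15), SCNN1G (-3.40 ± 0.23), RGCC (-3.00 ± 0.15) and SLAMF9 (-2.95 ± 0.12) had the most negative differences, and the cytokine IL7 (2.12 ± 0.17), RAB39B (2.07 ± 0.21), NBEAP1 (1.92 ± 0.25), XAF1 (1.88 ± 0.19) and MX2 (1.85 ± 0.10) the most positive. In the hypoxia response list 35 of 38 genes had a more negative effect in hypoxia and none a more positive one (median -0.97), with LOX at -2.52 ± 0.12, and 25 of 29 interferon-stimulated genes had a more positive and 1 a more negative one (median 0.93), with RSAD2 at 1.72 ± 0.08. When the correlation was estimated, these lists had adjusted p = 0.000331 and 0.0228. PTGS2 (-1.42 ± 0.16), HMOX1 (-1.73 ± 0.12), GDF15 (-0.78 ± 0.09) and VEGFA (-0.57 ± 0.12) had a smaller or more negative response in hypoxia, while HIF1A (0.10 ± 0.15) and PTGS1 (0.49 ± 0.22) did not pass. The S phase list had no call (16 of 46 more positive, 6 more negative, 18 and 7 adjusted over the list alone; median 0.19). The count was 3112 with the NO-sulindac arrays averaged. Across the 16003 genes, which are not independent replicates, the NO-sulindac effects in hypoxia and normoxia correlated at r = 0.461 (rho = 0.340): 1101 genes rose at both levels, 1304 fell at both and 626 passed in opposite directions, where independent calls would give 437 and 561 shared rises and falls. The interaction of sulindac with oxygen gave 1 gene, GUSBP4 (-0.81 ± 0.09, limma, adjusted p = 0.041), with 1283 at an unadjusted p under 0.05 and 800 by chance. Such an excess was larger for DMSO against untreated cells (2836 in hypoxia and 3229 in normoxia). The ATF4 list had a median difference of 0.15 for sulindac, with none of 33 genes passing over all genes and 8 adjusted over the list alone (adjusted p = 0.0511 with an estimated correlation).

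Genes that moved with oxygen in untreated cells were followed under each compound, with no array shared between the choice of genes and the test. The camera p-values of these sets were not adjusted for the number of sets and comparisons. Of the 3438 genes that rose in untreated hypoxia, 988 fell and 379 rose under NO-sulindac in hypoxia (median -0.086, camera p = 0.0298 with an estimated correlation). Of the 3566 that fell, 1042 rose and 344 fell (median 0.10, camera p = 0.0552 with an estimated correlation). Under NO-sulindac in normoxia the same sets moved the other way, with 1306 rises and 807 falls among the former (median 0.084, p = 0.0535 with an estimated correlation) and 1665 falls and 508 rises among the latter (median -0.18, p = 0.0643 with an estimated correlation). Limited to genes with an oxygen effect of at least 2-fold, the medians of the former and latter sets were -0.28 and 0.22 in hypoxia (camera p = 0.00441 and 0.0309 with an estimated correlation, a test added after seeing the data) and 0.63 and -0.40 in normoxia (p = 0.00121 and 0.0393) under NO-sulindac. The former set, so limited, had a median of 0.045 under sulindac in normoxia, with camera p = 0.000752 at the preset correlation and 0.157 at an estimated one. Across genes the oxygen effect in untreated cells correlated with the NO-sulindac effect at r = -0.284 in hypoxia and 0.303 in normoxia. Under sulindac the medians of both sets lay between -0.0085 and 0.018 at either oxygen level, with p = 0.236 with an estimated correlation for the set whose preset test passed, the genes that rose with hypoxia in normoxia sulindac.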

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

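Of the tests below, those of a signal ceiling and of a signal near the floor were chosen only after the result was seen.

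The results here stood out because the effect of NO-sulindac against DMSO differed between the oxygen levels in limma's interaction test, which 4902 genes passed. Hypoxia response genes showed the clearest difference (list median -0.97, adjusted p = 0.000331 with an estimated correlation): under NO-sulindac 37 of 38 rose in normoxia, whereas in hypoxia 20 fell and 3 rose. Relative to normoxia DMSO the list median was 0.956 in hypoxia DMSO, 0.813 in normoxia NO-sulindac and 0.809 in hypoxia NO-sulindac. The list was thus already raised in hypoxia without the compound, and under NO-sulindac it stood at a similar level at both oxygen levels. A signal ceiling shared by all probe sets would act on members near 14.5, the highest value of a probe set other than controls, but of 28 members at least 2 log2 units below it in hypoxia DMSO, 25 passed with a more negative effect in hypoxia, which argues against it. Exchanged oxygen labels of the NO-sulindac arrays would turn their oxygen difference against that of untreated cells, but the pair correlated at r = 0.379 across genes. A batch marked by the replicate number was tested against DMSO replicate 2 alone, where the list median in normoxia was still 0.85. That test covers the rise in normoxia and not the fall in hypoxia. Replicate differences also correlated with either sign between groups (r from -0.182 to 0.381). The number may thus not mark a batch, and the test cannot decide on one. A difference of the NO-sulindac cultures shared by both oxygen levels would cancel in the interaction, but one at a single oxygen level cannot be told apart from the compound, because the arrays titled 2 and 2b share 1 source name and may be 1 culture, and an effect of the compound that depends on the oxygen level stays open beside it.

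Interferon-stimulated genes differed in the opposite sense (list median 0.93, adjusted p = 0.0228 with an estimated correlation). Under NO-sulindac 21 of 29 rose and 1 fell in hypoxia, while 18 fell and 2 rose in normoxia. The fall of the list in normoxia did not pass camera with an estimated correlation (adjusted p = 0.12). The signal level argues against a floor: the median over members of the lowest group mean was 10.2, and 28 of 29 members lay above 6.32, the median of all probe sets (the lowest was at 5.98). Dependence on 1 array of hypoxia NO-sulindac was tested by leaving out either, and the list medians of 0.42 and 0.43 in hypoxia argue against it. A difference of 1 NO-sulindac culture at a single oxygen level cannot be told apart from the compound here either, for the same reason. A joint effect of the compound and low oxygen stays open beside it.

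Other genes with a more positive NO-sulindac effect in hypoxia than in normoxia were IL7 (2.12), RAB39B (2.07), NBEAP1 (1.92), XAF1 (1.88), MX2 (1.85), VASH2 (1.85), KCNT2 (1.82), NLRP3 (1.82), TRIM22 (1.82) and AGTR1 (1.81), as differences of log2 changes. A more negative one was seen for ANGPTL4 (-4.04), CXCR4 (-4.00), SCNN1G (-3.40), RGCC (-3.00), SLAMF9 (-2.95), SCNN1B (-2.90), SLC2A1 (-2.81), KISS1R (-2.80), LOC154761 (-2.78) and CFAP96 (-2.70). List medians of the difference were above 0 for ATF4 targets (0.47), G2 and M phase (0.41), ribosome biogenesis (0.34), mitochondrial ribosome and TCA cycle (0.26) and DNA repair (0.25). They were below 0 for metallothioneins and zinc handling (-0.45), glycolysis (-0.44), epithelial markers (-0.44), immediate early genes (-0.28), cholesterol synthesis and uptake (-0.26), angiogenic factors (-0.24), extracellular matrix (-0.19), autophagy and lysosome (-0.16) and NRF2 targets (-0.13). Estimating the correlation, the glycolysis, G2 and M phase, immediate early, angiogenic, extracellular matrix and ATF4 lists kept adjusted p-values of 0.0228, 0.0228, 0.0231, 0.0231, 0.0438 and 0.0438. The others had adjusted p = 0.0543 (ribosome biogenesis, and autophagy), 0.0824 (cholesterol), 0.103 (metallothioneins and zinc handling, and epithelial markers), 0.192 (NRF2), 0.201 (DNA repair) and 0.288 (mitochondrial ribosome) with an estimated correlation. The sulindac interaction gave 1 gene, GUSBP4 (-0.81), and the lists of ATF4 targets (0.15) and S phase genes (-0.064), with adjusted p = 0.0511 and 0.611 with an estimated correlation.

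Probe sets with no or several gene names, which no comparison of genes uses, also changed: of 8562, 1697 passed for NO-sulindac against DMSO in hypoxia and 3024 in normoxia, against 12 and 0 for sulindac.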

How the results depend on the processing

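Crossing the replicate numbers was the test chosen only after the result was seen. It gave 7056 and 6857 genes for hypoxia against normoxia in DMSO and untreated cells.

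The counts for hypoxia against normoxia (DMSO and untreated) and for NO-sulindac against DMSO and against sulindac in normoxia stayed within 1.5 times of their values under every alternative run, from 5370 to 9164. The correlation of the NO-sulindac effects ran from 0.4288 to 0.476. The vehicle and sulindac counts moved most. The cause was not tested, apart from settings that by construction use fewer samples or more probe sets. Counts are given below in the order sulindac in hypoxia, sulindac in normoxia and interaction of sulindac with oxygen. No filter gave 0, 1 and 0 genes. A filter at the median gave 19, 17 and 5. All probe sets gave 29, 16 and 5. Repeated quantile normalisation gave 4, 8 and 2. A variance prior with trend and robust gave 33, 24 and 4. Averaged NO-sulindac arrays gave 0, 1 and 0. Untreated cells as control gave 105, 1001 and 447. DMSO itself differed from untreated cells in 415 genes in hypoxia and 786 in normoxia in the main fit. The compared groups alone gave 0, 0 and 0. The replicate block gave 2 genes for sulindac in hypoxia and 0 for the interaction. DMSO against untreated in hypoxia gave 204 genes with no filter, 878 with the filter at the median, 1024 with all probe sets, 830 with trend and robust, 177 with averaged arrays and 2 with the groups alone. In normoxia it gave 2154, 1255 and 67 with all probe sets, trend and robust, and the groups alone. Averaging the NO-sulindac arrays gave 2795 genes against DMSO and 2505 against sulindac in hypoxia and 3112 for the interaction. The groups alone gave 2265 against sulindac in hypoxia.

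Leaving out 1 array at a time, with fewer samples, gave 2773 to 3806 genes for NO-sulindac against DMSO and 2680 to 3206 against sulindac in hypoxia. Sulindac gave 0 to 11 in hypoxia and 0 to 1 in normoxia, and its interaction 0 to 1. DMSO against untreated gave 11 to 404 in hypoxia and 251 to 663 in normoxia. The set that rose with hypoxia had a median of 0.0097 to 0.027 under sulindac in normoxia. With the filter at the median its median was 0.020 and it no longer passed, while the set that fell, at -0.0071, passed. The cause was not tested. Estimating the correlation in camera leaves the medians 0.10, 0.084, -0.18 and 0.018 as they were, but they no longer passed (camera p = 0.0552, 0.0535, 0.0643 and 0.236).

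Of the named genes, 4 reversed. With all probe sets ACACA under NO-sulindac in hypoxia was at 0.53, read from another of its probe sets, the one of smallest p. With untreated cells as control HNRNPL under sulindac in normoxia was at 0.10, and XRCC2 and ATG12 in the NO-sulindac interaction were at 0.42 and 0.13. Only the control arrays change in that setting, so these reversals reflect the difference between DMSO and untreated cells. Why the probe sets or the controls differ was not tested. Among gene calls, 34 were lost with the compared groups alone, 12 with averaged arrays and 9 with no filter. Among list calls, 73 were lost with an estimated correlation, 12 with the groups alone, 11 with all probe sets and 9 with untreated cells as control. Genes near the filter level, such as PTGS1, are limited by low signal.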

Other observations

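The test of an equal reduction of the oxygen difference by its slope was planned, while the tests of reversed signs, of the histone family and of oxygen within NO-sulindac or sulindac cells were chosen only after the result was seen.

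Within NO-sulindac cells hypoxia and normoxia still differed in 6242 genes (3420 rose, 2822 fell), but the hypoxia response list did not pass as a group (5 of 38 rose, 11 fell, median -0.040, adjusted p = 0.448). Both groups of this comparison are arrays titled 2 and 2b, which may be 1 culture per oxygen level. Its standard errors and p-values may thus leave out differences between cultures, and averaged arrays were not tried for it. When the correlation was estimated, 4 lists passed there. G2 and M phase genes were higher in hypoxia in 42 of 50 cases and lower in 1 (median 0.63, adjusted p = 0.00628), and S phase genes were higher in 29 of 46 (31 adjusted over the list alone; median 0.32, adjusted p = 0.0387). Interferon-stimulated genes were higher in 25 of 29 cases and lower in 1 (27 and 1 adjusted over the list alone; median 0.63, adjusted p = 0.0306), including EPSTI1 at 2.42, TRIM22 at 1.97 and IFI6 at 1.87. ATF4 targets were lower in 22 of 33 cases and higher in 2 (23 and 2 adjusted over the list alone; median -0.37, adjusted p = 0.0125). The largest rises were in TRMT2B (2.78 ± 0.0857), MATR3 (2.73 ± 0.0817), the survival gene BCL2A1 (2.64 ± 0.0852) and TMT1A (2.62 ± 0.0722), and the largest falls in RGCC (-2.72 ± 0.105), the interleukin receptor IL1RL1 (-2.48 ± 0.0766) and CXCR4 (-2.39 ± 0.107). The ACTB 3′ minus 5′ signal, a measure of RNA quality, also differed, at 1.86 ± 0.0016 (SD, n = 2) in hypoxia NO-sulindac and 2.26 ± 0.0783 in normoxia NO-sulindac, while that of GAPDH was 0.224 ± 0.0281 and 0.231 ± 0.000512. The oxygen difference within sulindac cells passed for 6612 genes (3025 rose, 3587 fell), with ACTB signals of 2.02 ± 0.000769 in hypoxia and 2.44 ± 0.0434 in normoxia and GAPDH signals of 0.195 and 0.243.

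Among 41 histone genes, a family taken more widely than the fixed list, 30 rose and 2 fell under NO-sulindac in hypoxia (median 0.62), and 28 rose and 2 fell in normoxia (median 0.52). None passed under sulindac at either oxygen level. H2AC8 rose by 2.13 and 2.24, H4C5 by 1.99 and 2.69, and H2BC5 by 1.31 and 1.86 in hypoxia and normoxia, while H3C3 (-1.78 and -2.40) and H1-3 (-1.22 and -1.77) fell. H1-3 also had the largest rise under DMSO against untreated cells in normoxia, so the size of its fall there depends on the control. With every probe set of these 41 genes tested, 34 of 47 rose and 2 fell at each oxygen level (medians 0.65 in hypoxia and 0.66 in normoxia). The family was counted and not tested as a list. The fixed core histone list, with every probe set, had medians of 0.0068 and -0.20 and passed camera at neither level. Probe sets of this family may not separate its similar sequences.

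TRMT2B, VHL and MATR3 were lower with DMSO than in untreated normoxia, and of these only TRMT2B passed for sulindac against DMSO. TRMT2B had a mean log2 level of 10.07 in untreated normoxia, 7.44 with DMSO, 6.64 with sulindac and 6.35 with NO-sulindac, and of 9.95 in hypoxia DMSO. VHL was at 9.14, 7.01, 6.57 and 6.26 in the same order, at 9.19 in hypoxia DMSO and at 7.78 in hypoxia NO-sulindac. MATR3 was at 9.30, 7.60, 7.49 and 6.76, and at 10.41 in hypoxia DMSO.

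That NO-sulindac reduced the oxygen difference of all genes alike was tested by the slope of that difference on the one in untreated cells. The slope was 0.333 over 15965 genes outside the hypoxia response list and 0.160 within its 38 genes (95 % confidence interval 0.0783 to 0.241), the former between the bounds of 0.2 and 0.4 set beforehand. A reduction turns no sign, but of 3694 genes that passed both within NO-sulindac and within untreated cells, 894 had oxygen differences of opposite sign, among them 17 of the 29 interferon-stimulated genes, which fell in untreated hypoxia. In these arrays the oxygen differences were thus not all reduced alike. The NO-sulindac arrays of an oxygen level may come from the same culture, however, and differences between cultures could also turn signs. The slope outside the list lay between its bounds, so neither test decides whether the compound reduced all genes alike.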
